A study of Mus musculus with 12 samples.

How the data were processed

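Total RNA from skeletal muscle of 12 mice was labelled with biotin and each sample was hybridized to its own 1-colour Affymetrix mouse array. The deposited table holds MAS5 signal, an intensity on a linear scale, for 45101 probe sets on 12 arrays. Per the labels, MAS5 was the tool used for every sample, and its version, background settings and scaling target are not stated. On every array the mean of all probe sets without the lowest and highest 2% was 500, so the authors' values carry a scaling to 1 target per array. No detection calls and no scanner files were used here. The number of arrays, 3 per group, limits the precision of every value.

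Samples were grouped by genotype and growth hormone (GH) as the labels give them: wild type (WT) and knockout of Stat5a and Stat5b (KO), each without and with GH. Titles give each array an animal number of its own, so the arrays were treated as separate animals, and nothing pairs the samples. The numbering style differs between the animals with and without GH.

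Values were taken as log2(signal + 25), where 25 is the pooled 25th percentile of all signals, rounded. The 64 control probe sets were left out of the gene tests, as were 932 probe sets with several gene symbols and 9160 with none. The other 34945 probe sets belong to 18193 genes, and 204 symbols were kept as in the platform annotation where the gene table had no newer one. Each gene was represented by the probe set with the highest mean over the 12 arrays. Genes whose mean lay above the 40th percentile of probe set means (a log2 value of 6.253) were kept, which left 12654 genes.

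Differential expression was tested with limma 3.58.1 in R 4.3.3 with statmod 1.5.0: lmFit with 1 mean for each of the 4 groups over all 12 arrays, 8 residual degrees of freedom, and eBayes with a mean trend and robust hyperparameters. The 6 comparisons were KO against WT without GH, KO against WT with GH, GH in WT, GH in KO, the interaction of genotype and GH, and the mean genotype effect, which averages both genotype differences. P-values are 2-sided and were adjusted by Benjamini-Hochberg over all genes kept, with a threshold of 0.05. "Rose" and "fell" refer to genes past that threshold. A value after ± is the standard error of a log2 fold change, or a standard deviation where a signal is given. Mean signals are arithmetic, while fold changes come from means of log2 values, so that their ratios differ where the arrays of a group vary.

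Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 24 lists with at least 5 genes kept. Camera with an estimated correlation and fry were run beside it. The lists cover STAT5 targets, GH and IGF signalling, androgen receptor and polyamine genes, slow fibre, fast fibre, atrophy, myogenesis, glycolysis, fatty acid oxidation, lipogenesis, respiratory chain, immediate early, STAT3 and acute phase, interferon, glucocorticoid, circadian and heat shock genes. Marker lists cover extracellular matrix, adipocytes, brown adipocytes, macrophages, lymphocytes, red cells, endothelium, smooth muscle, Schwann cells, keratinocytes, hepatocytes and sex-linked genes. Member counts are also given adjusted over the list alone. Some genes stand in more than 1 list, such as Lcn2 and Ddit4.

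Named genes followed a rule. It takes Stat5a and Stat5b, then in each comparison the 10 largest rises and the 10 largest falls past the threshold with no overlap between the replicates compared (no such condition for the interaction). It adds up to 4 members of each list with the smallest p past the threshold, or at most 2 members as values where none passed. Genes named outside the rule were chosen after their values were seen. In the report these are Igf1 in the 4 comparisons of 2 groups, Cish for KO against WT with GH and for GH in either genotype, Socs2 for GH in WT, Myh7 for KO against WT with GH and in the interaction, S100a9 for GH in KO, and Slc25a25 and Tmem267 in the comparisons of KO with WT. Identifiers without a gene name may be summarised by number. The design, the lists, this rule and all alternatives but the last 4 were set before the data were examined.

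Array quality was read from the 3 prime over 5 prime ratios of beta actin and Gapdh, the poly-A and hybridization control transcripts and the median signal. These were compared by exact permutation tests, 2-sided and adjusted over 9 measures for GH. With 3 arrays against 3 such a test cannot give a p under 0.1. Agreement between comparisons was measured across genes, which are not independent replicates, so no p is given.

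The method was tested on simulated data with 200 changed genes among 12654. The other genes of the respiratory chain list were shifted by 0.5 on the log2 scale besides. Between KO and WT without GH it recovered 55% of genes changed 1.5-fold, 82.5% of those changed 2-fold and 97.5% of those changed 4-fold. For GH in WT the shares were 41.2%, 68.8% and 97.5%, and for the interaction 15%, 46.2% and 92.5%. False calls made up 3.95%, 4.55% and 3.09% of the calls in these 3 simulations, and the shifted list was found in each. Of the lists not shifted, 1 also passed in the simulation of GH in WT and 0 in the other 2. The simulated noise was independent between genes and had the same spread in all 4 groups. In the real data the median standard deviation was 0.177 in WT and 0.0997 in KO with GH. Other splits of the real arrays for GH in WT gave up to 11 lists. The simulated rates of false calls and lists therefore need not hold for the real arrays.

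Alternatives changed 1 choice at a time. They were quantile normalization, median centring, no pseudocount, a pseudocount of 92, no filter, a filter at the 60th percentile, the mean of all probe sets of a gene, probe sets without the _x_at and _s_at suffixes, plain eBayes, array quality weights, a fit on only the groups compared, a threshold of 0.01, a change of at least 1.5-fold, leaving out each array, both other list tests, camera without Stat5a and Stat5b, and the upper part of mean signal for agreement. After the data were seen, 4 more were added: leaving out WT 1 and KO 3 together because they stood apart on principal components 4 and 3, the mean of the slow fibre list as a covariate, the actin ratio as a covariate, and the arrays with GH averaged to 1 sample per group. The data name no genome build, so no coordinates are given.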

Results

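The arrays measured RNA in skeletal muscle of mice with and without the transcription factors STAT5A and STAT5B, which pass the signal of the growth hormone receptor to the genome. The 12 arrays fell into 4 groups of 3: WT, KO, WT with GH and KO with GH. The series title asks how STAT5 bears on muscle growth and fibre composition, while a treatment label places the deletion in blood cells. The labels give no GH dose, duration, sex or age. Fast fibre contractile genes had a median signal of 49270 and a median percentile of 99.9 among the 18193 genes with a probe set. Markers of hepatocytes, keratinocytes, lymphocytes and red cells had medians at percentiles 26.8, 26.1, 27.2 and 9.66, and few of them were bright enough to test. The Y-linked gene Eif2s3y lay between 1106 and 1741 and Xist between 49.7 and 122 on the 12 arrays, and 0 of the 4 sex-linked genes passed limma's threshold in any comparison.

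Median signal per array was 97.1 to 101.5 with GH and 79.2 to 92.3 without. The arrays with GH also differed in ways unrelated to muscle genes. Poly-A control transcripts, bacterial RNAs added before labelling, had a geometric mean of 897 to 991 with GH and 224 to 268 without, a 3.78-fold difference (exact permutation p = 0.0022, adjusted p = 0.0028). The beta actin 3 prime over 5 prime ratio, a sign of RNA quality, was 0.887 to 1.01 with GH and 0.805 to 0.864 without (exact permutation p = 0.0022, adjusted p = 0.0028). Among the arrays with GH the actin ratio was 0.962 to 1.01 in KO and 0.887 to 0.932 in WT (exact permutation p = 0.1, the smallest the design allows). The Gapdh ratio was 0.795 to 0.86 with GH and 0.834 to 0.877 without (exact permutation p = 0.16, adjusted p = 0.16). With GH it was 0.954-fold in KO relative to WT (exact permutation p = 0.1), the opposite direction to actin. Hybridization controls were 0.872-fold with GH relative to without (exact permutation p = 0.015, adjusted p = 0.017). Replicates with GH were also more alike: the median standard deviation between them was 0.135 in WT and 0.0997 in KO on the log2 scale, against 0.177 in WT and 0.166 in KO without GH. GH treatment and the labelling batch cannot be told apart in this design. Among the arrays without GH, WT 1 stood apart on the 4th principal component (0.822 against -0.296 to 0.178 for the others) and KO 3 on the 3rd (-0.822 against -0.286 to 0.277), and limma gave them the 2 lowest array quality weights (0.319 and 0.421). All tests take the 3 arrays of a group as separate animals.

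**Figure D1:**
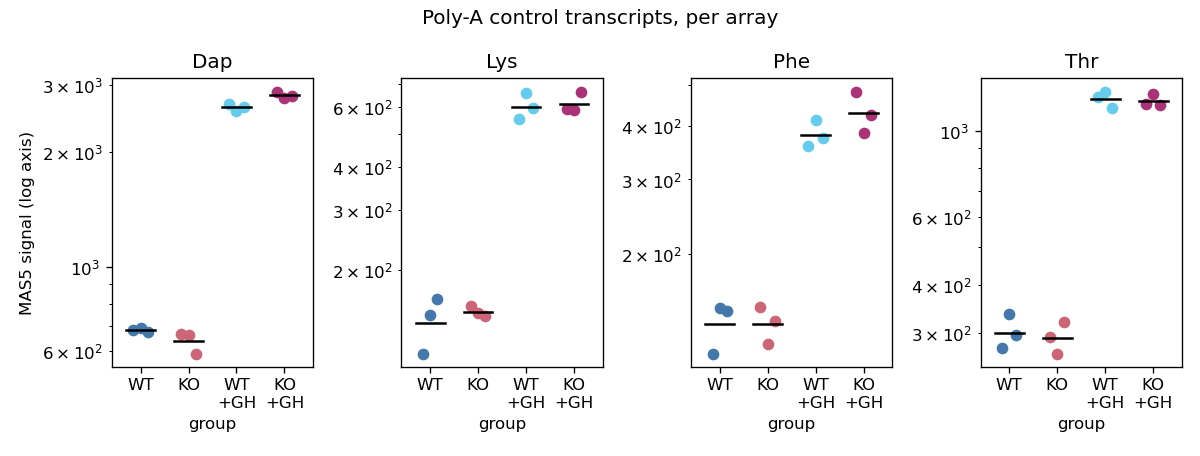
MAS5 signal (log axis) of 4 poly-A control transcripts on each array, by group, with points for arrays and bars for geometric means. All 6 arrays with GH lie above all 6 arrays without GH for each transcript.

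The deleted genes were lower in KO muscle with both of their probe sets. The brighter Stat5b probe set had a signal of 2820 ± 162 (SD, n = 3) in WT and 428 ± 63.7 in KO, which is 15.2% of WT. With GH it was 1794 ± 101 in WT and 362 ± 25.2 in KO, or 20.2%. Stat5a, by its brighter probe set, was 627 ± 90.5 in WT and 255 ± 97.5 in KO, or 40.6%, and with GH 402 ± 29.7 and 162 ± 33.5, or 40.2%. The other probe sets gave 15% and 30.9% for Stat5b and 39.8% and 35.7% for Stat5a. In the fit without GH, Stat5b fell by 2.66 ± 0.107 and Stat5a by 1.27 ± 0.208 on the log2 scale (adjusted p = 1.87e-09 and 0.00483). With only the WT and KO arrays in the fit, Stat5a had an adjusted p of 0.0576. With GH, Stat5b fell by 2.23 and Stat5a by 1.21 (adjusted p = 1.16e-08 and 0.00231).

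**Figure D2:**
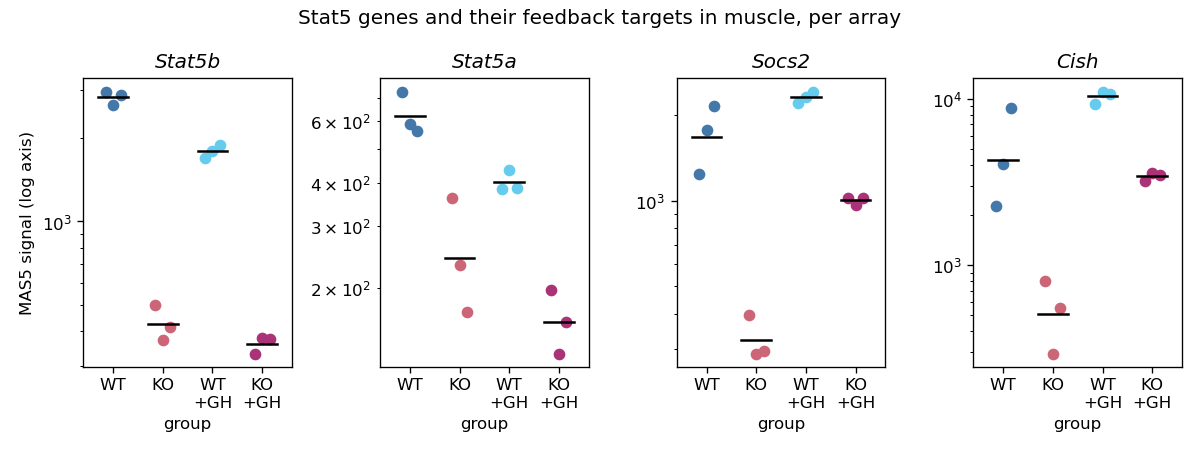
MAS5 signal (log axis) of Stat5b, Stat5a and the feedback genes Socs2 and Cish on each array, by group, with points for arrays and bars for geometric means. Arithmetic mean Socs2 signal was 1724 in WT, 328 in KO, 2315 in WT with GH and 1004 in KO with GH.

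Without GH, KO muscle had more RNA of 6 of 12 slow fibre genes than WT muscle and less RNA of the feedback inhibitors Socs2 and Cish. Slow myosin heavy chain Myh7 rose by 3.60 ± 0.62 on the log2 scale, slow troponins Tnnc1 and Tnni1 by 3.08 ± 0.49 and 3.03 ± 0.484, and the slow calcium pump Atp2a2 by 0.73 ± 0.124 (0.12 to 0.73 over its 5 probe sets). Socs2 and Cish fell by 2.29 ± 0.159 and 3.02 ± 0.461, with -2.29 to -0.93 over the 5 probe sets of Socs2. The polyamine enzyme Odc1 fell, from a signal of 13090 to 6443 (SE of the log2 change 0.147). In all, 98 genes were higher and 86 lower in KO, with 25 and 25 of them changed at least 2-fold.

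Of 12 slow fibre genes 6 rose, 0 fell and 6 did not pass (6 rose adjusted over the list alone), and the list was higher by camera (adjusted p = 2.61e-12, but adjusted p = 0.171 with an estimated correlation). Their level varied between WT animals: the mean of the 6 that rose was 8.88 to 10.92 in WT and at least 12.02 in KO. Without WT 3 the adjusted p was 0.0883 for Myh7, 0.0692 for Tnnc1 and 0.0651 for Tnni1, and without KO 3 it was 0.084, 0.0663 and 0.0616. Myh7 also lost its call without KO 1 (0.0604) and without KO 2 (0.0757). With only the WT and KO arrays in the fit the adjusted p was 0.361 for Myh7, 0.296 for Tnnc1, 0.292 for Tnni1 and 0.105 for Atp2a2. The mean of all its probe sets gave Atp2a2 an adjusted p of 0.163. Of 14 fast fibre genes 0 passed limma's threshold (camera adjusted p = 0.566), and Myh2 had a log2 fold change of -0.54 ± 0.152 (adjusted p = 0.109, and 0.0193 without KO 1).

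**Figure D3:**
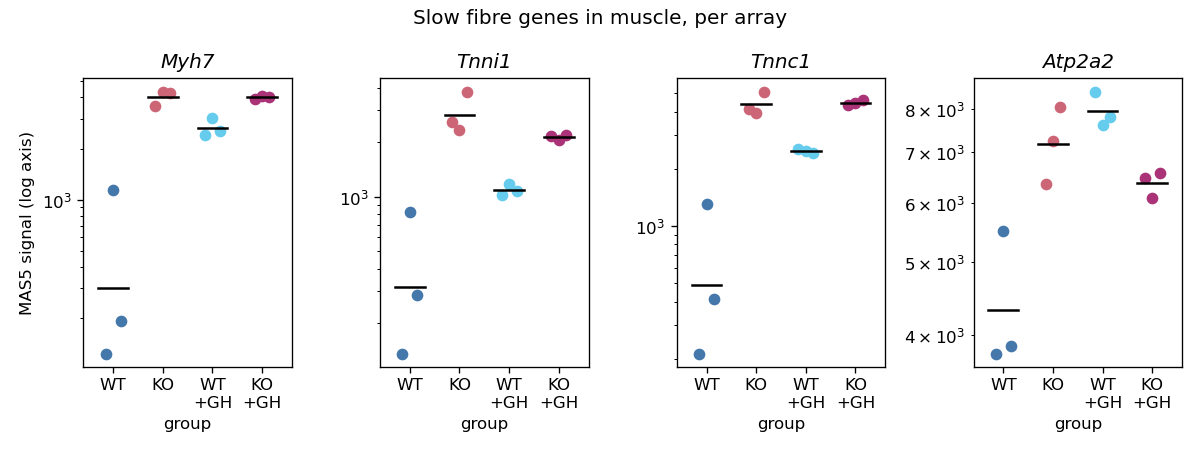
MAS5 signal (log axis) of 4 slow fibre genes on each array, by group, with points for arrays and bars for geometric means. Arithmetic mean Myh7 signal was 483 in WT, 4048 in KO, 2658 in WT with GH and 4006 in KO with GH.

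Among 18 STAT5 target genes 3 fell, 0 rose and 15 did not pass (4 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0512, adjusted p = 0.375 with an estimated correlation, and by fry adjusted p = 0.0228 on the lower side), and 10 of the 18 had a positive log2 fold change. Igf1, the growth factor that GH induces, chosen after its value was seen, had a log2 fold change of -0.49 ± 0.196 (adjusted p = 0.335, and -0.75 to -0.17 over its 4 probe sets), and -0.77 without KO 2 (adjusted p = 0.0227). Socs2 kept its call with only the WT and KO arrays in the fit, whereas Cish (adjusted p = 0.27), Odc1 (0.065) and Kcnf1 (0.0606) did not. The androgen receptor and polyamine list was lower, with 2 of 7 members past the threshold (3 adjusted over the list alone; adjusted p = 0.00132, and adjusted p = 0.213 with an estimated correlation). In the GH and IGF signalling list 3 genes rose and 2 fell, the latter being Stat5a and Stat5b (camera adjusted p = 0.654, and by fry adjusted p = 0.00907 on the lower side). Of 22 immediate early genes 3 rose and 1 fell (camera adjusted p = 0.258). Junb and Dusp1, which are switched on quickly by many stimuli, rose by 1.03 ± 0.13 and 0.42 ± 0.067, the latter with an adjusted p of 0.141 when only the WT and KO arrays were in the fit.

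Further lists passed camera's threshold with few or no members called. Glucocorticoid responsive genes were lower (1 of 16 fell, 4 adjusted over the list alone; adjusted p = 0.00132, and adjusted p = 0.171 with an estimated correlation). Interferon responsive genes were higher (1 of 17 rose, 3 adjusted over the list alone; adjusted p = 0.00138, and adjusted p = 0.403 with an estimated correlation), with an adjusted p of 0.0705 without KO 1. Heat shock genes were higher and fatty acid oxidation genes lower, with 0 of 16 and 0 of 24 members past limma's threshold (0 and 1 adjusted over the list alone). Their adjusted p was 0.00262 and 0.00999, and adjusted p = 0.669 and 0.695 with an estimated correlation. The heat shock list had an adjusted p of 0.33 without WT 2 and 0.436 without KO 2, and the fatty acid list 0.344 without WT 2 and 0.2 without KO 3. By fry the interferon, heat shock and fatty acid lists had an adjusted p of 0.152, 0.412 and 0.406.

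Outside the lists, the largest rises included the growth factor carrier Fgfbp1 (4.01-fold, SE of the log2 change 0.171) and the protease inhibitor Serpinb1a (log2 change 1.75 ± 0.186, but 0.08 by its other probe set). The largest falls included the matrix protein Npnt (-1.85 ± 0.124, and -1.85 to -0.54 over 4 probe sets), the protease Casp12 (-1.74 ± 0.151) and the fatty acid ligase Acsl3 (-1.64 ± 0.197). These 5 genes had adjusted p-values from 1.46e-06 to 0.000395. With only the WT and KO arrays in the fit, which changes the spread and also lowers the residual degrees of freedom from 8 to 4, 23 genes were higher and 16 lower. The count of lower genes was 130 without KO 1 and 56 without KO 2, and with the slow fibre mean as a covariate, chosen after the data were seen, 30 genes were higher and 30 lower. Without WT 1 and KO 3 together, chosen likewise, 156 were higher and 121 lower.

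With GH, KO muscle differed from WT muscle in 10 of 22 immediate early genes. The transcription factor Egr1 rose by 3.43 ± 0.136 on the log2 scale, its co-repressor Nab2 by 2.82 ± 0.151, the ERK phosphatase Dusp5 by 3.83 ± 0.246 and the muscle GTPase Rrad by 5.05 ± 0.267. Mean Rrad signal was 154 in WT with GH and 5793 in KO with GH. The glucocorticoid-linked transcription factor Klf15 fell by 1.55 ± 0.105 and the ubiquitin ligase Fbxo32, known from muscle wasting, by 1.25 ± 0.112 (-1.58 to -0.43 over its 3 probe sets). In all, 306 genes were higher and 267 lower in KO, with 87 and 48 of them changed at least 2-fold.

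Of 22 immediate early genes 9 rose, 1 fell and 12 did not pass (11 and 2 adjusted over the list alone). The list was higher (adjusted p = 6.36e-08, and adjusted p = 0.21 with an estimated correlation), with Junb up by 2.01 ± 0.13, Btg2 by 2.28 ± 0.236 and Jun by 0.81 ± 0.0962. The actin ratio was 1.08-fold higher in KO than in WT on these arrays, while the Gapdh ratio was 0.954-fold. Of 17 STAT3 and acute phase genes 4 rose and 1 fell (4 and 1 adjusted over the list alone), among them the STAT3 inhibitor Socs3 (2.22 ± 0.303) and Saa3 (1.54 ± 0.222). That list was higher (adjusted p = 0.0218, and adjusted p = 0.276 with an estimated correlation), with an adjusted p of 0.0588 without WT_GH 1. Of 17 myogenic genes 3 rose (4 rose and 1 fell adjusted over the list alone; adjusted p = 0.0152, and adjusted p = 0.276 with an estimated correlation): Ankrd1 (1.41 ± 0.163), Myf6 (0.68 ± 0.0748) and Myod1 (1.05 ± 0.175), the last with an adjusted p of 0.308 with the mean of all probe sets. The myogenic list had an adjusted p of 0.0696 with a filter at the 60th percentile.

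**Figure D4:**
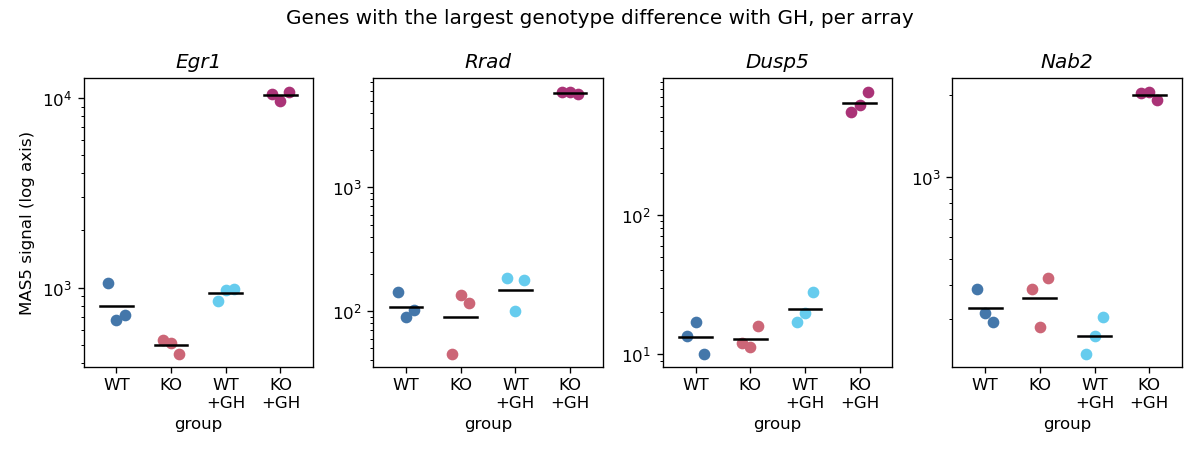
MAS5 signal (log axis) of Egr1, Rrad, Dusp5 and Nab2 on each array, by group, with points for arrays and bars for geometric means. Arithmetic mean Egr1 signal was 815 in WT, 496 in KO, 934 in WT with GH and 10328 in KO with GH.

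Of 16 glucocorticoid responsive genes 4 fell, 0 rose and 12 did not pass (5 fell and 1 rose adjusted over the list alone), among them the mTORC1 inhibitor Ddit4 (-1.69 ± 0.193), Klf15 and Sgk1 (-0.87 ± 0.171). The list was lower (adjusted p = 0.0407, and adjusted p = 0.276 with an estimated correlation). Its adjusted p was 0.0883 without WT_GH 1, 0.06 without WT_GH 3, 0.0685 with quantile normalization, 0.0696 with a filter at the 60th percentile, 0.16 with the mean of all probe sets and 0.146 without _x_at and _s_at probe sets. Of 24 fatty acid oxidation genes 3 fell (3 adjusted over the list alone), namely the regulators Ppara (-0.98 ± 0.171) and Ppargc1a (-0.88 ± 0.183) and the mitochondrial carrier Ucp3 (-1.16 ± 0.219). That list was lower (adjusted p = 0.0152, and adjusted p = 0.694 with an estimated correlation), with an adjusted p of 0.142 without WT_GH 1 and 0.131 by fry; Ppargc1a had an adjusted p of 0.054 without WT_GH 2 and Ucp3 of 0.0788 with the mean of all probe sets. Among 19 atrophy genes 2 rose and 5 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.383).

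Fast fibre and respiratory chain genes were lower as lists, with 0 of 14 and 0 of 26 members past limma's threshold (0 and 0 adjusted over the list alone). Their adjusted p was 0.0152 and 0.0492, and adjusted p = 0.694 with an estimated correlation for both. The fast fibre list had an adjusted p of 0.413 without WT_GH 1, 0.789 with quantile normalization and 0.333 by fry. The respiratory chain list had 0.6 with quantile normalization, 0.85 without WT_GH 1, 0.06 without WT_GH 3, 0.115 without KO_GH 1 and 0.134 without KO_GH 2. It also had 0.13 with median centring, 0.0526 with a pseudocount of 92, 0.0609 with no filter, 0.079 with a filter at the 60th percentile, 0.064 with the mean of all probe sets, 0.397 by fry and 0.0505 without WT 1 and KO 3 together, chosen after the data were seen. Schwann cell markers were higher as a list, with 0 of 6 members called and 0 adjusted over the list alone (adjusted p = 0.0218, and adjusted p = 0.276 with an estimated correlation), and had an adjusted p of 0.0686 without WT_GH 1, 0.0537 without WT_GH 3, 0.0609 with no filter and 0.0696 with a filter at the 60th percentile. Of 12 slow fibre genes 0 passed limma's threshold (camera adjusted p = 0.36), and Myh7 had a log2 fold change of 0.59 ± 0.62 (adjusted p = 0.713, and 0.00058 with only the arrays with GH in the fit). Socs2 fell by 1.19 ± 0.159 (-1.28 to -0.07 over its 5 probe sets) and lost its call with the mean of all probe sets, while Cish had a log2 fold change of -1.59 ± 0.461 (adjusted p = 0.104, and 2.17e-07 with only the arrays with GH in the fit) and Igf1 of -0.32 ± 0.196 (adjusted p = 0.47). Myh7, Cish and Igf1 were chosen here after their values were seen. The GH and IGF signalling list, which holds Stat5a and Stat5b, had an adjusted p of 0.405 by camera and 0.00704 by fry, on the lower side.

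The counts with GH changed with the fit. With the arrays with GH averaged to 1 sample per group, an alternative chosen after the data were seen, 1 value is compared with 1 value and the spread comes only from the arrays without GH; 15 genes were then higher and 5 lower (Stat5b, Slc25a25, Klf15, Aldh9a1 and 1700001O22Rik, of which Slc25a25 lies outside the rule for names and was chosen after its value was seen). With the actin ratio as a covariate, chosen likewise, 85 genes were higher and 59 lower, whereas with only the arrays with GH in the fit 618 were higher and 682 lower. Without any 1 of the 6 arrays with GH the count of higher genes was 192 to 231 and that of lower genes 161 to 175, the lowest in both cases without KO_GH 3. The count of lists was 2 without WT_GH 1 and 5 without WT_GH 3, against 8.

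GH in WT muscle went with higher RNA of acute phase, glucocorticoid responsive and atrophy genes and with lower RNA of 14 of 19 lipid synthesis genes. The acute phase lipocalin Lcn2 rose by 4.30 ± 0.173 on the log2 scale, the neutrophil proteins S100a8 and S100a9 by 3.69 ± 0.305 and 3.83 ± 0.182, and the metallothioneins Mt1 and Mt2 by 2.98 ± 0.284 and 3.62 ± 0.341. The fatty acid synthase Fasn fell by 1.45 ± 0.192. In all, 927 genes were higher and 1489 lower, so that 38.4% were higher. With each array centred on its median 1113 were higher and 1097 lower, or 50.4% higher.

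Of 16 glucocorticoid responsive genes 15 rose (15 adjusted over the list alone; adjusted p = 1.12e-23, and adjusted p = 0.000388 with an estimated correlation), among them Cebpd (2.55 ± 0.0851, and 1.21 by its other probe set), Ddit4 (3.65 ± 0.193) and Klf15 (1.70 ± 0.105). Of 17 STAT3 and acute phase genes 13 rose (13 rose and 1 fell adjusted over the list alone; adjusted p = 9.14e-16, and adjusted p = 0.00203 with an estimated correlation), including the cytokine receptor Osmr (1.47 ± 0.102). Of 19 atrophy genes 11 rose and 1 fell (11 and 2 adjusted over the list alone; adjusted p = 8.81e-11, and adjusted p = 0.0125 with an estimated correlation), including the transcription factor Foxo1 (1.47 ± 0.128). Some of these genes stand in several of the 3 lists. Of 22 immediate early genes 8 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 1.48e-05, and adjusted p = 0.134 with an estimated correlation), including Zfp36 (1.67 ± 0.119). Of 17 interferon genes 5 rose (6 adjusted over the list alone; adjusted p = 0.0157, and adjusted p = 0.339 with an estimated correlation), including Ifit1 (1.56 ± 0.206). The interferon list had an adjusted p of 0.0533 without WT 1, 0.131 with a filter at the 60th percentile, 0.0892 with the mean of all probe sets, 0.0763 without _x_at and _s_at probe sets, 0.0548 by fry and 0.0538 without WT 1 and KO 3 together, the last chosen after the data were seen.

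Slow fibre genes rose with GH in WT, 8 of 12 (8 adjusted over the list alone; adjusted p = 3.5e-06, and adjusted p = 0.214 with an estimated correlation), with Myh7 up 7.98-fold (SE of the log2 change 0.62) and Tnnc1 up by 2.27 ± 0.49 on the log2 scale. With only the WT arrays in the fit their adjusted p was 0.0964 and 0.0976. Of 18 STAT5 targets 6 rose and 3 fell (8 and 4 adjusted over the list alone; adjusted p = 0.0129, adjusted p = 0.136 with an estimated correlation and 0.0743 with the mean of all probe sets), among them Socs3 (2.17 ± 0.303) and the survival gene Bcl2l1 (1.07 ± 0.119, and 0.22 to 1.07 over 3 probe sets). Socs2, Cish and Igf1, chosen after their values were seen, had log2 fold changes of 0.45 ± 0.159, 1.25 ± 0.461 and 0.10 ± 0.196 (adjusted p = 0.0582, 0.0922 and 0.765), with 0.21 to 0.73 over the 5 probe sets of Socs2 and -0.16 to 0.31 over the 4 of Igf1. Without WT 3 the adjusted p was 0.0127 for Socs2 and 0.00882 for Cish, and Socs2 had 0.0476 with quantile normalization. The myogenic list, not past camera's threshold (adjusted p = 0.0751), had 0.0213 by fry on the higher side. Stat5b fell by 0.65 ± 0.107.

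Lipid synthesis genes, adipocyte markers and macrophage markers were lower as lists with GH in WT. Of 19 lipogenesis genes 14 fell and 1 rose (14 and 2 adjusted over the list alone; adjusted p = 1.71e-07, and adjusted p = 0.134 with an estimated correlation), including Agpat2 (-1.49 ± 0.154) and Dgat2 (-0.86 ± 0.084) of triglyceride synthesis. Of 11 adipocyte markers 7 fell (7 adjusted over the list alone; adjusted p = 0.000735, and adjusted p = 0.139 with an estimated correlation), including Cidec (-1.02 ± 0.129). Of 15 macrophage markers 8 fell and 1 rose (11 and 1 adjusted over the list alone; adjusted p = 0.000159, and adjusted p = 0.257 with an estimated correlation), including Cd74 (-1.16 ± 0.115) and Csf1r (-0.64 ± 0.118). These changes cannot be separated from the poly-A, actin ratio and median signal differences of the same arrays. With the arrays with GH averaged, 93 genes were higher and 55 lower; with the actin ratio as a covariate the counts were 260 and 227, and with the slow fibre mean 418 and 415, all 3 chosen after the data were seen. The count of lower genes was 988 without WT_GH 3.

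In KO muscle GH went with the same 3 list changes that passed both forms of camera in WT, and with higher RNA of 13 immediate early genes. Rrad rose by 5.63 ± 0.267 on the log2 scale, Egr1 by 4.31 ± 0.136, the growth factor Hbegf by 3.86 ± 0.132, Socs3 by 3.87 ± 0.303 and Lcn2 by 4.65 ± 0.173. The pericyte and fibroblast protein Cd248 fell by 2.17 ± 0.148 and the clock repressor Nr1d1 by 1.98 ± 0.134. In all, 1130 genes were higher and 1948 lower, so that 36.7% were higher. With each array centred on its median 1359 were higher and 1362 lower, or 49.9% higher.

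Of 16 glucocorticoid responsive genes 13 rose (15 adjusted over the list alone; adjusted p = 3.74e-19, and adjusted p = 0.000852 with an estimated correlation), including Fkbp5 (2.32 ± 0.176). Of 17 STAT3 and acute phase genes 14 rose (14 rose and 1 fell adjusted over the list alone; adjusted p = 2.11e-17, and adjusted p = 0.00143 with an estimated correlation), including Cebpd (2.67 ± 0.0851, but 0.35 by its other probe set). Of 22 immediate early genes 13 rose and 2 fell (14 and 2 adjusted over the list alone; adjusted p = 5.19e-10, and adjusted p = 0.0322 with an estimated correlation), including Myc (1.60 ± 0.138). Of 19 atrophy genes 10 rose and 1 fell (11 and 3 adjusted over the list alone; adjusted p = 9.5e-08, and adjusted p = 0.0322 with an estimated correlation), including Gadd45a (2.57 ± 0.162). Of 18 STAT5 targets 8 rose and 3 fell (8 and 4 adjusted over the list alone; adjusted p = 0.00218, and adjusted p = 0.072 with an estimated correlation). Socs2 rose by 1.56 ± 0.159 and Cish by 2.68 ± 0.461 on the log2 scale, while Igf1 had a log2 fold change of 0.28 ± 0.196 (adjusted p = 0.337, and -0.35 to 0.44 over its 4 probe sets), and 0.55 without KO 2 (adjusted p = 0.0171). Cish and Igf1 were chosen here after their values were seen. Of 7 androgen receptor and polyamine genes 4 rose (4 adjusted over the list alone; adjusted p = 0.000292, and adjusted p = 0.0759 with an estimated correlation), including Azin1 (0.90 ± 0.112). Of 17 myogenic genes 7 rose and 1 fell (8 and 2 adjusted over the list alone; adjusted p = 0.00218, and adjusted p = 0.0834 with an estimated correlation), including Ankrd1 (3.49 ± 0.163).

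Lipid synthesis, adipocyte, macrophage, respiratory chain and fast fibre genes were lower as lists with GH in KO, while the neutrophil gene S100a9, chosen after its value was seen, rose by 3.02 on the log2 scale. Of 19 lipogenesis genes 11 fell and 1 rose (13 and 1 adjusted over the list alone; adjusted p = 4.5e-06, and adjusted p = 0.0949 with an estimated correlation), including Srebf1 (-1.03 ± 0.0913) and Scd1 (-0.90 ± 0.111). Of 11 adipocyte markers 7 fell (7 fell and 1 rose adjusted over the list alone; adjusted p = 0.000678, and adjusted p = 0.0949 with an estimated correlation), including Retn (-1.68 ± 0.158). Of 15 macrophage markers 9 fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 0.00218, and adjusted p = 0.422 with an estimated correlation), including Cd74 (-1.59 ± 0.115). Of 26 respiratory chain genes 12 fell and 1 rose (17 and 1 adjusted over the list alone; adjusted p = 0.00165, and adjusted p = 0.567 with an estimated correlation), with an adjusted p of 0.701 with quantile normalization. Of 14 fast fibre genes 10 fell and 1 rose (12 and 1 adjusted over the list alone; adjusted p = 0.00395, and adjusted p = 0.56 with an estimated correlation), but with quantile normalization the list pointed up (adjusted p = 0.451). Schwann cell markers were higher, with 4 of 6 past the threshold (4 adjusted over the list alone; adjusted p = 0.00218, and adjusted p = 0.072 with an estimated correlation). The actin ratio, the poly-A signal and the median signal differed between the same arrays. With the arrays with GH averaged 179 genes were higher and 100 lower, and with the actin ratio as a covariate 94 were higher and 29 lower, both chosen after the data were seen.

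Lists that did not pass camera's threshold in either GH comparison were GH and IGF signalling, glycolysis, fatty acid oxidation, circadian, heat shock, extracellular matrix, brown adipocyte, endothelial and smooth muscle genes. Of 17 glycolysis genes 2 rose and 3 fell with GH in WT and 1 rose and 7 fell in KO (adjusted p = 0.252 and 0.076). Of 15 extracellular matrix genes 1 rose and 3 fell in WT and 0 rose and 3 fell in KO (adjusted p = 0.18 and 0.107, the latter 0.0283 by fry). Of 8 smooth muscle genes 1 rose and 2 fell in WT and 3 rose and 3 fell in KO (adjusted p = 0.726 and 0.537). Of 5 brown adipocyte genes 0 rose and 1 fell in WT and 0 passed limma's threshold in KO (adjusted p = 0.0751 and 0.661). Of 16 heat shock genes 1 rose and 2 fell in WT and 3 fell in KO (adjusted p = 0.726 and 0.363). Among lists too small for camera, 1 of 3 lymphocyte markers fell in WT and 2 fell in KO, 1 of 3 keratinocyte markers rose in each, and 1 of 4 hepatocyte markers rose in WT and 0 passed limma's threshold in KO. The lone red cell marker tested, Alas2, had log2 fold changes of 0.17 ± 0.228 and 0.61 ± 0.228 (adjusted p = 0.643 and 0.0651).

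The interaction asked whether the genotype effect differed with GH, which a batch shift common to both genotypes leaves unchanged. It was positive for 79 genes and negative for 39. Rrad (5.25 ± 0.378), Egr1 (4.10 ± 0.192), Dusp5 (3.84 ± 0.347), Nab2 (2.71 ± 0.213) and Hbegf (2.23 ± 0.186) had the higher GH log2 fold change in KO. The mitochondrial ATP carrier Slc25a25 (-2.47 ± 0.136, with 3 probe sets from -2.47 to -0.16), Klf15 (-1.42 ± 0.148), Aldh9a1 (-1.47 ± 0.239) and Fbxo32 (-0.99 ± 0.158, with 3 probe sets from -1.36 to -0.21) had the lower GH log2 fold change in KO. Of the 79 genes, 70 rose with GH in KO and 21 in WT, while 2 fell in KO and 20 in WT. Of the 39, 29 rose in WT and 2 in KO, while 3 fell in WT and 17 in KO.

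In the interaction 4 of 22 immediate early genes were higher and 1 lower (10 and 2 adjusted over the list alone; adjusted p = 3.29e-05, and adjusted p = 0.237 with an estimated correlation). Among them were Egr1 and Klf6 (0.96 ± 0.15, and 0.42 to 0.96 over 5 probe sets), the latter with an adjusted p of 0.0519 with the mean of all probe sets. Saa3 (2.34 ± 0.314) was 1 of 2 STAT3 and acute phase genes higher of 17 (4 adjusted over the list alone; adjusted p = 0.00478, and adjusted p = 0.237 with an estimated correlation), and the list had an adjusted p of 0.0993 with the mean of all probe sets and, chosen after the data were seen, 0.051 without WT 1 and KO 3 together. Azin1 (1.09 ± 0.158) was the 1 androgen receptor and polyamine gene higher of 7 (3 adjusted over the list alone; adjusted p = 0.000299, and adjusted p = 0.237 with an estimated correlation), and lost its call with the mean of all probe sets, having -0.20 to 1.09 over 3 probe sets. Slow fibre genes were lower, with 1 of 12 past the threshold, Atp2a2 (-1.05 ± 0.175), and 6 adjusted over the list alone (adjusted p = 2.55e-06, and adjusted p = 0.237 with an estimated correlation). Atp2a2 also lost its call with the mean of all probe sets, having -1.13 to 0.18 over 5 probe sets, and Myh7, chosen after its value was seen, had a value of -3.01 ± 0.877 (adjusted p = 0.249, and 8.5e-08 without WT 2). Interferon genes were lower with 0 of 17 past limma's threshold and 0 adjusted over the list alone (adjusted p = 0.000537, and adjusted p = 0.237 with an estimated correlation).

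Myogenic genes were higher in the interaction, with 2 of 17 higher and 1 lower (3 and 1 adjusted over the list alone), among them Ankrd1 (1.41 ± 0.231). Schwann cell genes were higher with 0 of 6 past limma's threshold, and respiratory chain genes lower with 0 of 26 (0 and 0 adjusted over the list alone). These lists had adjusted p = 0.034, 0.0401 and 0.034, and adjusted p = 0.237, 0.237 and 0.936 with an estimated correlation. The myogenic list had 0.0588 without WT 1, 0.073 without KO 2, 0.0641 without WT_GH 3, 0.0568 without KO_GH 1, 0.0826 with a filter at the 60th percentile and 0.0993 with the mean of all probe sets. The Schwann cell list had 0.0588 without WT 1, 0.104 without WT 2, 0.16 without KO 1, 0.0767 without WT_GH 1, 0.0641 without WT_GH 3, 0.0568 without KO_GH 1, 0.0792 without KO_GH 3, 0.178 with no filter and 0.166 with a filter at the 60th percentile. The respiratory chain list had 0.355 without WT 1, 0.148 without KO 3, 0.771 without WT_GH 1, 0.0721 without KO_GH 1 and 0.0814 without KO_GH 2. It also had 0.879 with quantile normalization, 0.069 with median centring, 0.0647 with a filter at the 60th percentile, 0.0993 with the mean of all probe sets and, chosen after the data were seen, 0.763 without WT 1 and KO 3 together. By fry the adjusted p was 0.124 for the slow fibre, STAT3, interferon and Schwann cell lists, 0.142 for the myogenic and 0.616 for the respiratory chain list. The count of lower genes was 21, 22 and 24 without WT_GH 1, 2 and 3 and 17, 20 and 20 without KO_GH 1, 2 and 3, against 39, and the count of lists was 5 without KO_GH 1. With the arrays with GH averaged, 3 genes were higher and 1 lower, namely Egr1, Rrad, Nab2 and Slc25a25; with the actin ratio as a covariate 45 were higher and 9 lower, both chosen after the data were seen.

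The mean genotype effect, 6 KO against 6 WT arrays within GH status, averages the differences with and without GH, so that a gene can pass through a change in 1 of them alone. Serpinb1a rose by 2.13 ± 0.131 on the log2 scale (0.85 by its other probe set), Fgfbp1 by 1.98 ± 0.121 and Junb by 1.52 ± 0.0916. The potassium channel subunit Kcnf1 fell by 2.60 ± 0.236, Socs2 by 1.74 ± 0.112 (-1.74 to -0.50 over its 5 probe sets), Cish by 2.30 ± 0.326 and Odc1 by 0.70 ± 0.104. In all, 364 genes were higher and 312 lower in KO. Averaging the arrays with GH left 42 higher and 31 lower, the slow fibre mean as a covariate 164 and 140, and the actin ratio 140 and 122, all chosen after the data were seen.

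Averaged over GH status, 5 of 12 slow fibre genes rose (5 adjusted over the list alone; adjusted p = 1.4e-06, and adjusted p = 0.419 with an estimated correlation), including Tnni1 (1.99 ± 0.342) and Tnnc1 (1.96 ± 0.347). Of 22 immediate early genes 9 rose and 1 fell (11 and 2 adjusted over the list alone; adjusted p = 1.55e-06, and adjusted p = 0.188 with an estimated correlation), including Fos (1.14 ± 0.153). Of 16 glucocorticoid responsive genes 5 fell and 1 rose (6 and 1 adjusted over the list alone; adjusted p = 0.000768, and adjusted p = 0.188 with an estimated correlation), including Klf15 (-0.85 ± 0.0741). Of 24 fatty acid oxidation genes 4 fell (5 adjusted over the list alone; adjusted p = 0.000768, and adjusted p = 0.494 with an estimated correlation), including Ucp3 (-0.86 ± 0.155) and Ppargc1a (-0.67 ± 0.129). Of 17 myogenic genes 2 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.0364, and adjusted p = 0.421 with an estimated correlation), including Myf6 (0.51 ± 0.0529). Heat shock genes were higher and fast fibre genes lower, with 0 of 16 and 0 of 14 members past limma's threshold and 0 and 0 adjusted over the list alone. Their adjusted p was 0.0039 and 0.0272, and adjusted p = 0.542 and 0.625 with an estimated correlation.

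Some of these lists depended on single arrays or settings. The myogenic list had an adjusted p of 0.0503 with median centring, 0.135 with a filter at the 60th percentile, 0.0505 without WT 2, 0.129 without WT 3, 0.065 without WT_GH 3 and 0.0626 without KO_GH 1. The heat shock list had 0.0705 without WT 2 and 0.0592 without KO 2, and by fry 0.223, against 0.0684 for the fatty acid list. By fry alone the STAT5 target, GH and IGF signalling and atrophy lists passed, on the lower side, with 0.0298, 0.000676 and 0.0298 (camera 0.134, 0.408 and 0.134). The fast fibre list had 0.408 with quantile normalization, 0.0503 with median centring, 0.0525 with the mean of all probe sets, 0.313 by fry, 0.0505 without WT 2, 0.131 without KO 1, 0.0592 without KO 2, 0.34 without WT_GH 1 and 0.0626 without KO_GH 1.

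Genotype effects with and without GH shared direction across part of the genes. Across 12654 genes, which are not independent replicates, Pearson's r was 0.242 and Spearman's rho 0.162; in the upper part by mean signal r was 0.366. Both comparisons had 50 genes higher (2.37 by chance for independent lists) and 45 lower (1.81 by chance). Only 3 genes were called in opposite directions (4.15 by chance), and all 3 are named here, some chosen after their values were seen. Slc25a25 was 0.91 ± 0.0961 without GH and -1.55 ± 0.0961 with GH (-1.55 to 0.26 over its 3 probe sets), Tmem267 was -0.77 ± 0.109 and 0.77 ± 0.109, and Egr1 was -0.66 ± 0.136 and 3.43 ± 0.136. Egr1 without GH lost its call without KO 2 (adjusted p = 0.0591) and without KO 3 (0.084). GH effects in WT and KO had r of 0.648 and rho of 0.615 across genes, and r of 0.752 in the upper part by mean signal. They shared 547 higher genes (82.8 by chance), 936 lower genes (229 by chance) and 19 in opposite directions (276 by chance), a count to which any batch difference between the arrays with and without GH adds.

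**Figure D5:**
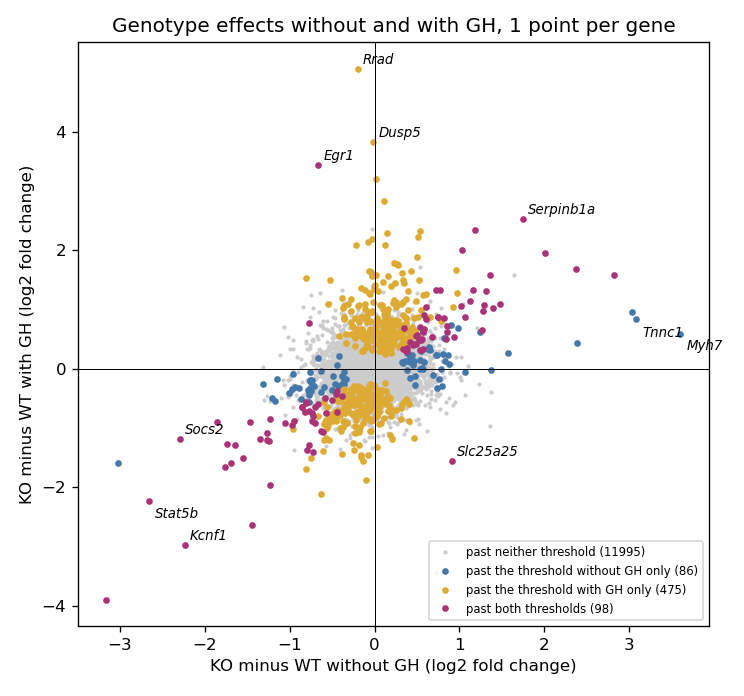
Log2 fold change of KO against WT without GH (x axis) and with GH (y axis), 1 point per gene, coloured by the comparison in which it passed the threshold. Of the 12654 genes 98 passed in both, and Egr1, Slc25a25 and Tmem267 did so with opposite signs.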

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

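The tests of the 3 patterns, the averaging of the arrays with GH, the actin covariate and the counts of other splits were chosen only after the results were seen; the tests of the interaction were planned.

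The interaction of genotype and GH differed from 0 for 79 genes on the higher side and 39 on the lower side, by limma's test of the difference itself. The interaction was positive for Rrad (5.25 on the log2 scale), Egr1 (4.10), Dusp5 (3.84), Sgms2 (3.18), Nab2 (2.71), Saa3 (2.34), Dusp2 (2.31), Hbegf (2.23), Srxn1 (2.21), Btg2 (2.13), Ankrd1 (1.41), Myod1 (1.41), Gadd45a (1.14), Socs2 (1.10), Azin1 (1.09), Junb (0.98) and Klf6 (0.96). It was negative for Slc25a25 (-2.47), Krt88 (-2.33), Apold1 (-1.64), Aldh9a1 (-1.47), Klf15 (-1.42), B330016D10Rik (-1.39), Slc7a8 (-1.38), Rarres1 (-1.35), Ciart (-1.33), Mss51 (-1.29), Fst (-1.06), Atp2a2 (-1.05), Fbxo32 (-0.99), Cldn5 (-0.97) and Nr1d1 (-0.88). A negative value can mean a smaller rise or a larger fall in KO, the latter for Nr1d1. Of these 32 genes 20 kept their calls whichever array was left out, 23 kept them with both other choices of probe sets, and 4 (Rrad, Egr1, Nab2 and Slc25a25) kept them with the arrays with GH averaged, where the spread comes only from the arrays without GH. The 3 probe sets of Slc25a25 ranged from -2.47 to -0.16, those of Fbxo32 from -1.36 to -0.21 and of Azin1 from -0.20 to 1.09, and the 5 of Atp2a2 from -1.13 to 0.18 and of Klf6 from 0.42 to 0.96. The calls lost to the mean of all probe sets were those of Ciart, Mss51, Socs2, Azin1, Atp2a2, Myod1, Fst, Klf6 and Nr1d1, with an adjusted p of 0.0591, 0.0519, 0.122, 0.0911, 0.49, 0.634, 0.0739, 0.0519 and 0.054. Median centring also ended the calls of Ciart (0.0556) and Mss51 (0.0519). The calls lost to leaving out 1 array were those of Apold1, Ciart, Cldn5, Fst, Gadd45a, Junb, Krt88, Mss51, Nr1d1, Rarres1, Slc7a8 and Socs2, for which the highest adjusted p was 0.0703, 0.132, 0.0588, 0.144, 0.0976, 0.0526, 0.071, 0.148, 0.128, 0.102, 0.0935 and 0.0891. By camera the lists that differed were slow fibre (adjusted p = 2.55e-06), immediate early (3.29e-05), androgen receptor and polyamine (0.000299), interferon (0.000537), STAT3 and acute phase (0.00478), myogenic (0.034), respiratory chain (0.034) and Schwann cell genes (0.0401). With an estimated correlation their adjusted p was 0.237, or 0.936 for the respiratory chain.

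Poly-A control transcripts, which no comparison of genes uses, were 3.78-fold higher on the arrays with GH.

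The first pattern is the smaller spread between replicates with GH. Of 6327 genes in the upper part of mean signal, 77 in WT and 74 in KO ranged over more than 1 log2 unit between replicates, against 15 in WT and 2 in KO with GH. Lower measurement noise with GH stays open: the ratio of the median spread with GH to that without was 0.949 in the dimmest of 5 equal sets of genes, where background weighs most, and 0.516 in the brightest. GH evening out the genes that respond to it stays open too: among the variable genes 717 had an unadjusted p for GH of 0.05 or more and an excess spread of at most 1.17 with GH, against 1.37 in KO without GH, but a large spread itself raises that p (the standard error of variable genes was 1.47 times that of others). Arrays that carry shared or pooled RNA remain a candidate explanation, since genes that vary most between WT animals had an excess spread of at most 1.15 with GH and 1.45 in KO without GH; a more uniform set of animals was not tested and stays open.

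The second pattern is the low slow fibre signal of WT muscle without GH. The mean of the 6 called genes ranged over 2.04 log2 units within WT, which is 0.849 of the difference of 2.40 between KO and WT, and the lowest correlation between these genes across the 3 WT arrays was 0.9. The range within KO was 0.377. The standard deviation of this mean was 1.04 in WT, 0.195 in KO, 0.0171 in WT with GH and 0.0195 in KO with GH. A varying share of slow fibres in the pieces of muscle taken may account for part of the difference. The wide spread on which this rests was seen only in WT without GH. Loss of STAT5 as the whole cause, alike with and without GH, stays open: the difference with GH was 0.463, and the change in the difference had a permutation p of 0.11. The labels do not name the muscle taken.

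The third pattern is the higher immediate early response of KO with GH. With the actin ratio in the fit Egr1 (4.10 to 3.96) and Klf6 (0.96 to 0.947, adjusted p = 0.0456) kept their calls. Junb (0.98 ± 0.183 to 1.03 ± 0.229, adjusted p = 0.0892) and Btg2 (2.13 ± 0.333 to 1.87 ± 0.404, adjusted p = 0.101) lost theirs, as the folds held while their errors grew. The genes were paired for this test only after the outcome was seen. The slope of the ratio also comes only from differences within groups, and the Gapdh ratio was not tried as a covariate. RNA quality as the whole cause therefore stays open for these genes. A lone sample or pool behind the 3 KO arrays with GH stays open, as averaging the arrays with GH leaves the folds as they were and lowers the residual degrees of freedom from 8 to 4, so that the 4 of 118 interaction calls left decide nothing. A stronger STAT3 response without STAT5 is a biological candidate explanation that stays open, with a camera adjusted p of 0.237 for the STAT3 list with an estimated correlation.

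Other splits of the same arrays were counted for each comparison. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 184 genes between KO and WT without GH (highest other 11; 1 of 10 splits gave as many), 573 with GH (highest other 0; 1 of 10), 2416 for GH in WT (0; 1 of 10) and 3078 for GH in KO (0; 1 of 10). For lists the real and highest other counts were 6 and 11 without GH (7 of 10 splits gave as many), 8 and 6 with GH (1 of 10), 10 and 11 for GH in WT (4 of 10) and 13 and 12 for GH in KO (1 of 10). For the mean genotype effect 1 of 100 splits gave as many as 676 genes (highest other 206), so chance is excluded as long as the arrays with GH are separate animals. Among the 8 of these splits that keep the genotype groups with GH intact the other 7 gave 108 to 206 genes, and 8 are too few for a share under 0.05. For its lists, 39 of 100 gave as many as 7 (highest other 11), so chance is not excluded. For the interaction 6 of 100 splits gave as many as 118 genes (highest other 676). All 5 others keep the genotype groups with GH intact and so carry the genotype difference with GH, while splits that do not keep them intact gave at most 3 genes, so this count does not settle whether chance is excluded. The split with 676 genes mirrors the labels in 1 GH status, which turns the interaction into the mean genotype effect. For its lists, 25 of 100 gave as many as 8 (highest other 12), so chance is not excluded.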

How the results depend on the processing

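Leaving out WT 1 and KO 3 together, both covariates and the averaging of the arrays with GH were chosen only after the results were seen; the other alternatives were planned. Except where stated, the cause was not tested. Over all alternatives, named genes kept direction and side of the threshold in 8597 cases, lost the call in 1280, gained it in 40 and reversed in 16, and lists kept theirs in 883, lost it in 142 and reversed in 1.

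Counts of genes are given as higher and lower. Their order is KO against WT without GH, with GH, GH in WT, GH in KO, interaction and mean genotype effect. Ranges with 1 array left out are given for every comparison, and other counts only where they moved by more than 1.5 times. Leaving out 1 array gave 66 to 131 and 56 to 130; 192 to 231 and 161 to 175; 638 to 987 and 988 to 1450; 774 to 1078 and 1299 to 1698; 59 to 90 and 17 to 53; 254 to 448 and 210 to 362. Lists then numbered 5 to 9, 2 to 9, 10 to 14, 13 to 15, 5 to 11 and 5 to 10. A threshold of 0.01 gave 45 and 43, 181 and 142, 490 and 676, 633 and 999, 15 lower in the interaction, and 212 and 164, and a change of at least 1.5-fold gave 57 higher without GH, 196 and 158, 506 and 590, 620 and 652, and 115 and 103, both by their stricter construction. Plain eBayes gave 54 and 57 without GH and 18 lower in the interaction. Array quality weights gave 150 higher without GH, 655 and 707 with GH, 122 and 92 in the interaction, and 575 and 499 for the mean effect. Only the groups compared gave 23 and 16 without GH and 618 and 682 with GH, where the spread came from 6 arrays and 4 residual degrees of freedom in place of 8. Without WT 1 and KO 3 there were 156 higher without GH, 499 and 529 with GH, and 92 lower in the interaction. The slow fibre covariate gave 30 and 30 without GH, 418 and 415 for GH in WT, and 164 and 140 for the mean effect. The actin covariate gave 85 and 59 with GH, 260 and 227, 94 and 29, 45 and 9, and 140 and 122. Averaging the arrays with GH gave 23 and 16, 15 and 5, 93 and 55, 179 and 100, 3 and 1, and 42 and 31, from 8 samples in place of 12.

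Lists past the threshold with GH numbered 5 with quantile normalization and 4 with a filter at the 60th percentile. In the interaction they numbered 5 with that filter, 5 with the mean of all probe sets and 2 with fry. With an estimated correlation they numbered 0, 0, 3, 4, 0 and 0. Agreement across genes rose to r = 0.366 for genotype and 0.752 for GH in the upper part of mean signal.

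Reversed values were, with quantile normalization, Eno3 (0.0437) and the fast fibre list (adjusted p = 0.451) for GH in KO. With the mean of all probe sets they were Hadhb (0.0799), Sdhc (0.0706) and Lox (-0.13) for GH in WT and Hadhb (0.22), Cycs (0.0200), Dcn (0.14) and Stat5b (0.0744) for GH in KO. Without _x_at and _s_at probe sets they were Ifi35 (-0.11) for GH in WT and Ifi35 (-0.0840) and Laptm5 (0.24) for GH in KO. Igf1 for GH in WT was -0.0387 to 0.231 when 1 array was left out, lowest without WT 2, and was not called. With the actin covariate Igf1 (-0.23) and Rrad (-0.32) for GH in WT and Pmp22 (-0.0362) and Igf1 (-0.31) for GH in KO reversed. Signal over background limits dim genes: the median spread within WT was 0.289 on the log2 scale in the dimmest of 5 equal sets of genes and 0.128 in the brightest. No paired analysis was possible because each array carries an animal number of its own.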

Other observations

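The test of genes near the Stat5 locus took its final form only after its result was seen, and Sln, Gamt, Ache, H2-Eb1, Ighm, Slc25a25, and Rrad, Egr1 and Per2 with GH in WT were chosen after their values were seen.

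Sln, Gamt and Ache differed in KO in the same direction with and without GH. Sarcolipin (Sln), which inhibits the calcium pump, rose by 1.16 ± 0.176 and 1.32 ± 0.176 on the log2 scale. Gamt, which makes creatine, rose by 1.29 ± 0.1 and 1.08 ± 0.1, and acetylcholinesterase (Ache) by 0.75 ± 0.0987 and 0.87 ± 0.0987. The adjusted p-values of these genes lay between 6.14e-06 and 0.00228. Slc25a25 rose with GH by 1.80 ± 0.0961 in WT and fell by 0.66 ± 0.0961 in KO, with 0.97 to 1.80 and -0.66 to 0.81 over its 3 probe sets. Rrad and Egr1 had GH log2 fold changes of 0.38 ± 0.267 and 0.22 ± 0.136 in WT (adjusted p = 0.355 and 0.292), and Egr1 had 0.41 without WT 1 (adjusted p = 0.00871).

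Some clock and vessel genes passed limma's threshold with GH, in both directions, while neither list passed camera's. Of 17 circadian genes 7 rose and 2 fell in WT and 6 rose and 3 fell in KO, with camera adjusted p of 0.063 and 0.156 for the list. The repressor Nr1d1 fell by 1.10 ± 0.134 in WT and by 1.98 ± 0.134 in KO, and Per2 rose by 1.15 ± 0.265 in WT (0.03 to 1.15 over its 3 probe sets) and by 1.48 ± 0.265 in KO. Of 12 endothelial genes 4 rose and 3 fell in WT and 2 rose and 3 fell in KO (camera adjusted p = 0.529 and 0.796). The VEGF receptor Flt1 rose by 1.48 ± 0.126 and 1.36 ± 0.126 (0.79 to 1.75 over 4 probe sets in KO) and its relative Kdr fell by 1.51 ± 0.127 and 0.91 ± 0.127. The labels give no time of day.

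H2-Eb1, a class II histocompatibility gene, had signals of 46.5, 810 and 934 on the WT arrays and 126, 937 and 122 on the KO arrays. With GH it was 750, 819 and 802 in WT and 732, 721 and 710 in KO. Ighm was 8150, 4160 and 16600 on the KO arrays and 2630, 2650 and 2740 on the KO arrays with GH. In WT it was alike between replicates in both states, at 8890, 8850 and 7710 without GH and 7060, 6310 and 7110 with GH. Its 5 probe sets gave log2 fold changes from -1.5 to 0.757 for KO against WT with GH.

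Strain alleles carried along with the targeted locus could alter genes near Stat5a and Stat5b. Of 200 tested genes within 100 genes of the locus 1 was called in both genotype comparisons with the same sign, against 92 of 12432 others (odds ratio 0.674, interval 0.0168 to 3.89, Fisher's exact p = 1). That gene was Stat3, the tested gene directly beside Stat5a and Stat5b. Its log2 fold changes were 0.74 ± 0.143 without GH and 0.87 ± 0.143 with GH. Its 4 probe sets ranged from 0.62 to 1.41 without GH and from -0.11 to 1.73 with GH. Without GH it had an adjusted p of 0.0148, and 0.0559 without WT 3, 0.0687 without KO 2 and 0.0647 without KO 3. With so few genes called near the locus the test leaves this open.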
